A study of Homo sapiens with 16 samples.

How the data were processed

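BT474 tumours were dissected from immunodeficient mice after 30 days of doxycycline, total RNA was isolated with TRIZOL and 100 ng was labelled as sense target and hybridised to Affymetrix HuGene-1_0-st-v1 arrays, per the labels' protocols. The 16 arrays comprise 6 CTRL miR, 7 SHP2 miR1 and 3 SHP2 miR2 tumours, 1 array each, grouped as the labels state. The deposited table holds 1 log2 signal per transcript cluster and array. The log2 scale is inferred from the deposited values, which run from 1.54 to 13.63 with array medians of 5.21 to 5.41. R 2.10 and the oligo package 1.8 are named in the submitters' processing notes. The background correction and the normalization between arrays are not given in the sources used here.

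Of 28869 transcript clusters, 19310 are listed with 1 gene symbol, 1752 with several symbols and 7807 with none. Clusters with 1 symbol were used, and each of the 685 genes with more than 1 cluster was represented by the cluster with the highest mean over all arrays, which left 18377 genes. No filter on low values was applied. A linear model with the 3 groups was fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 13 residual degrees of freedom). The contrasts were both SHP2 miRs against CTRL miR with equal weight on each miR, each SHP2 miR against CTRL miR, and SHP2 miR1 against SHP2 miR2. P-values were adjusted after Benjamini-Hochberg within a contrast, and a gene passed (was called) at an adjusted p below 0.05. PTPN11 was also tested with an exact two-sided permutation test. Intervals are at the 95% level. For arrays, depth is not defined, and their number limits the precision. Plots were drawn with matplotlib 3.10.9.

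The comparisons, tests, gene lists and the rule for named genes were chosen before the data were examined. Named genes are PTPN11, a fixed panel of 15 (MYC, ZEB1, LIN28B, ERBB2, ERBB3, EGFR, SOX2, CD44, GAB1, GAB2, PTPN6, DUSP6, SPRY4, CCND1 and ESR1), and the 12 largest rises and 12 largest falls past the threshold for both miRs, with the same sign for each miR. They further include the 6 largest rises and falls for each single miR, for the genes called with both by the smaller of the changes, and between the miRs, and at most 4 members with the smallest adjusted p of each list described. The 28 gene lists were ERK pathway output, immediate-early and dissection stress genes, MYC targets of ribosome biogenesis and growth, cell cycle and proliferation, ERBB receptors with their ligands and SHP2 partners, 17q12 amplicon, luminal epithelial identity, oestrogen receptor response, basal and myoepithelial, epithelial-mesenchymal transition, stem and progenitor genes, mammary secretory differentiation, FOXO targets, hypoxia response, cholesterol and fatty acid synthesis, unfolded protein and amino acid response, interferon response, antigen presentation, p53 targets, NF-kB and inflammatory cytokines, oxidative phosphorylation, fibroblast and matrix (host), endothelial (host), macrophage and myeloid (host), adipocyte (host), skeletal muscle (host), lymphocyte (host) and blood cells (host). Lists with the word host are markers of cell types that a dissected tumour can hold. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a contrast, and again with an estimated correlation and with fry. Members were counted over all genes tested and adjusted over the list alone.

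The fit was tested on simulated values for 18377 genes with known changes of 0.5, 1 or 2 log2 units. It recovered 68.7%, 100% and 100% for both miRs, 68.7%, 100% and 100% for miR1 and 43.3%, 98.5% and 100% for miR2, with 7, 9 and 12 false calls. Between the miRs, where no change was simulated, it made 0 calls. On 28 simulated lists camera called 1, the list that had been shifted. Apart from the set changes, the simulated values were independent noise for each gene. They held no correlation between genes and no structure among the tumours beyond the groups. The simulations can therefore not show how many false calls of genes or lists either would give.

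Alternatives chosen before the data were examined were quantile normalization, centring each array on its median, leaving out the third of genes with the lowest mean, all clusters of the table, an intensity trend with a robust prior, array weights, the replicate number as a block, a score of the fibroblast, endothelial and macrophage lists as a covariate, leaving out each tumour in turn, only the groups compared, weighting the miRs by number of tumours, and controls divided between the miRs. Further alternatives were chosen after seeing the data. These were control tumours 2 and 5 alone, the array set as a block, each array set alone, a score of kidney line markers as a covariate (alone and with the set as a block), cyclic loess between arrays, and random lists matched on expression. The array sets come from the expression profiles, since the labels give no batch or date.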

Results

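BT474 is a human breast cancer cell line with amplified ERBB2 (HER2). BT474 cells carrying a doxycycline-inducible lentiviral vector were grown as tumours in the mammary fat pad of immunodeficient mice, and the vector expressed either a control microRNA hairpin (CTRL miR) or 1 of 2 hairpins against SHP2 (SHP2 miR1, SHP2 miR2). SHP2, encoded by PTPN11, is a tyrosine phosphatase that passes signals from receptor tyrosine kinases to the RAS-ERK pathway. After tumours had formed, the mice drank doxycycline at 2 g per L for 30 days, and total RNA of each tumour (100 ng) was measured on a human gene array. There were 6 CTRL miR, 7 SHP2 miR1 and 3 SHP2 miR2 tumours, 16 arrays in all. The series asks how these tumours differ in expression with and without SHP2. Values are log2 signals, with array medians between 5.21 and 5.41 and a range within arrays of 1.54 at the lowest to 13.63 at the highest. All changes are log2 differences with standard errors (SE), tested with limma over 18377 genes and adjusted after Benjamini-Hochberg. The labels number the tumours but do not tie them to animals, so the p-values of single genes measure the spread between these tumours. The camera p-values of the gene lists set a list against the other genes, at a preset correlation between genes. They therefore mainly reflect how a list differs from other genes, not the spread between tumours, and can be small with few controls. Values with an estimated correlation are given beside them where these were run. The number of arrays, in particular 3 for miR2, limits the precision.

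Expression profiles of the arrays also differed in ways that the groups do not give. Control tumours 1, 3, 4 and 6 stood apart from the other 12 arrays. IRS4, an insulin receptor adaptor with little expression in most adult tissues, had a log2 signal of 7.14 to 8.29 in those 4 tumours, 3.16 and 3.77 in control tumours 2 and 5, and 2.97 to 3.91 in the 10 knockdown tumours. The homeobox gene HOXD10 had 7.31 to 7.83 in the 4 tumours, 4.17 and 3.43 in control tumours 2 and 5, and 3.27 to 3.90 with knockdown. Values for control tumours 2 and 5 alone are therefore given for the lists that passed and for many of the named genes. They come from a fit that was chosen after seeing the data and that leaves out the other 4 controls. The arrays further fell into 2 sets. Set A held control tumours 1 to 3 and miR1 tumours 1 to 4, and set B held the other 9 arrays, which include all 3 miR2 tumours. The mean of 5 noncoding RNAs (RNU4-1, RNU4-2, RPPH1, RMRP and SNORA65) was 8.19 to 8.39 in set A and 6.81 to 7.21 in set B. The sets were read from the expression profiles, so the difference between them was not tested. Some values with the set as a block and within sets are given below. Finally, the values of miR2 tumours 1 and 3 were compressed, with an SD over all clusters of 1.89 in each against 1.95 to 2.07 in the other 14 arrays.

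PTPN11, the targeted gene (transcript cluster 7958846), was lower in every knockdown tumour than in every control. Its log2 signal was 8.40 ± 0.16 (SD, n = 6) in the controls, 6.93 ± 0.19 (SD, n = 7) with miR1 and 6.46 ± 0.10 (SD, n = 3) with miR2. The ranges were 8.23 to 8.61, 6.59 to 7.18 and 6.34 to 6.53. With miR1 the change was -1.47 ± 0.097 (SE, limma adjusted p = 5.11e-08), so that 36.0% of the control signal remained (95% interval 31.3% to 41.5%). With miR2 it was -1.94 ± 0.12 (SE, adjusted p = 6.97e-09), and 26.1% remained (21.9% to 31.2%). A two-sided exact permutation test gave p = 0.000583 for miR1 and p = 0.0119 for miR2, in each case the smallest that the 1716 and 84 permutations allow. PTPN11 was 0.46 ± 0.12 (SE) higher with miR1 than with miR2 (adjusted p = 0.0115, exact p = 0.00833). That difference no longer passed without miR2 tumour 3 (0.40, adjusted p = 0.0896), with a score of host cell markers as a covariate (0.43, adjusted p = 0.166) or with cyclic loess between arrays (0.27, adjusted p = 0.135), the latter chosen after seeing the data. Against control tumours 2 and 5 alone the changes were -1.33 (adjusted p = 6.03e-05) and -1.79 (adjusted p = 1.26e-06). Within set A the miR1 change was -1.49 (adjusted p = 0.0144); within set B it was -1.43 (adjusted p = 0.000495) with miR1 and -1.97 (adjusted p = 6.27e-06) with miR2.

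**Figure D1:**
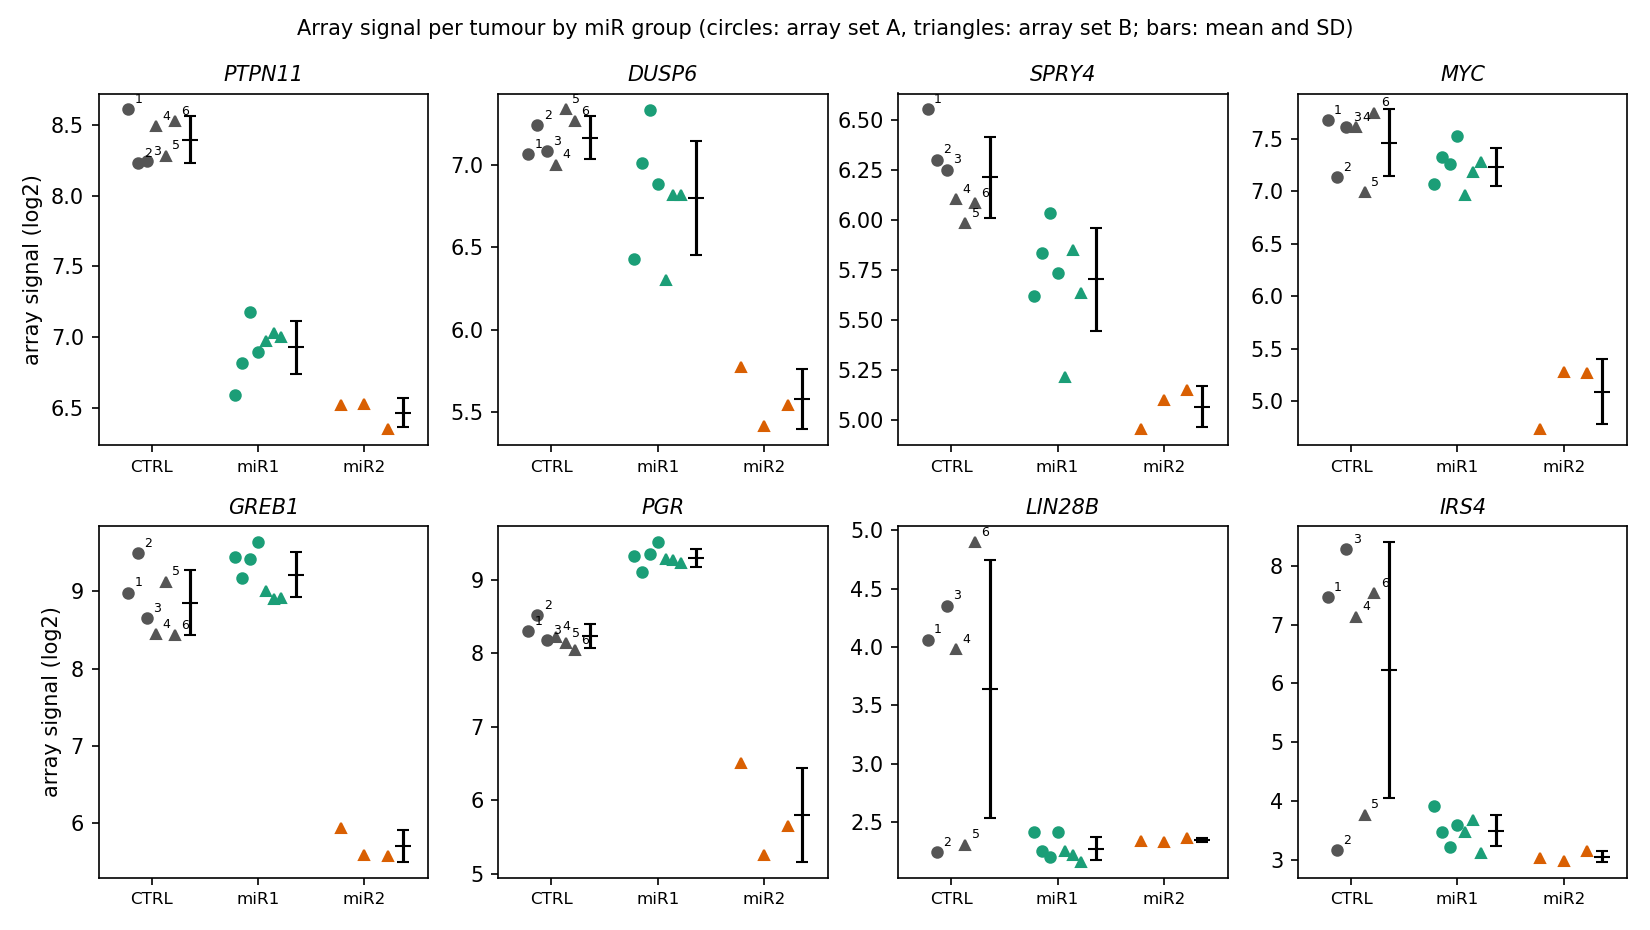
Log2 signal of PTPN11, DUSP6, SPRY4, MYC, GREB1, PGR, LIN28B and IRS4 in each of the 16 tumours by group, with circles for set A, triangles for set B, numbers on the control tumours and bars for the mean and SD of each group. PTPN11 lies between 6.34 and 7.18 in the 10 knockdown tumours and between 8.23 and 8.61 in the controls, MYC lies between 4.73 and 5.28 with miR2 and between 6.96 and 7.75 in the other 13 tumours, and IRS4 lies between 7.14 and 8.29 in control tumours 1, 3, 4 and 6.

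Tumours with either SHP2 hairpin were compared with the controls first, with equal weight on the hairpins. A value for both hairpins is the mean of their 2 changes, so it can pass where 1 hairpin carries it. ERK-induced genes were lower. DUSP6, the phosphatase that ERK signalling induces and that inactivates ERK, changed by -0.97 ± 0.13 (SE), adjusted p = 9.83e-05. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, changed by -0.83 ± 0.11 (SE), adjusted p = 0.000148. The ETS transcription factors ETV4 (-0.79, adjusted p = 0.000222) and ETV5 (-0.74, adjusted p = 0.000338) fell as well. Of the 18 measured genes of the ERK pathway output list, 0 rose, 7 fell and 11 did not pass over all genes tested (0 and 7 adjusted over the list alone). The list was lower as a group (mean -0.31, camera adjusted p = 0.000299, adjusted p = 0.205 with an estimated correlation). With control tumours 2 and 5 alone its mean was -0.35 (adjusted p = 4.49e-09), with DUSP6 at -1.10 (adjusted p = 0.00694), SPRY4 at -0.76 (adjusted p = 0.0313) and ETV5 at -0.63 (adjusted p = 0.122). Within set B the mean was -0.25 (adjusted p = 0.00221). The transcription factor MYC fell by 1.30 ± 0.13 (SE, adjusted p = 7.68e-06) on average, and by 0.90 (adjusted p = 0.00529) against control tumours 2 and 5. Its mean hides a difference between the hairpins, given further down. Among the 32 MYC targets of ribosome biogenesis and growth, 0 rose, 24 fell and 8 did not pass over all genes tested (0 and 30 adjusted over the list alone), with POLR1B (-0.65) and WDR43 (-0.59) among them (mean -0.41, camera adjusted p = 4.97e-14, adjusted p = 0.135 with an estimated correlation). Of 35 cell cycle genes, 0 rose, 26 fell and 9 did not pass over all genes tested (0 and 32 adjusted over the list alone), including the apoptosis inhibitor BIRC5 (-0.63) and the topoisomerase TOP2A (-0.54) (mean -0.46, camera adjusted p = 5.98e-15, adjusted p = 0.262 with an estimated correlation). With control tumours 2 and 5 alone the means of these 2 lists were -0.19 and -0.15 (adjusted p = 1.33e-06 and 0.000285), and 0 of their members passed on their own.

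The largest rises in the mean of both hairpins were MUC19, a gel-forming mucin (2.15 ± 0.24 (SE), adjusted p = 2.31e-05), the synaptic vesicle protein gene SYT1 (1.41), CEP126 (1.33), VSTM2A (1.29), GLYATL2 (1.26), the netrin receptor UNC5C (1.21) and OTOGL (1.20). PVALB (1.14), GRIK2 (1.14), the membrane oestrogen receptor GPER1 (1.13), FAM83B (1.13) and MUC1 (1.12) completed the 12. In 6 of them miR1 alone did not pass, namely VSTM2A (0.15, adjusted p = 0.701), OTOGL (0.19, adjusted p = 0.643), GRIK2 (0.33, adjusted p = 0.155), PVALB (0.43, adjusted p = 0.16), SYT1 (0.45, adjusted p = 0.231) and MUC1 (0.52, adjusted p = 0.112), and miR2, with 1.71 to 2.42, carried most of their mean. PVALB (1.01, adjusted p = 0.0782) and MUC1 (0.48, adjusted p = 0.38) no longer passed against control tumours 2 and 5, while the other 10 still did. The 12 largest falls were IRS4 (-2.95 ± 0.60 (SE), adjusted p = 0.00316), HOXD10 (-2.82), RADX (-2.77), SMARCA1 (-2.44), ECHDC1 (-2.38), PLS3 (-2.20), HSPA4L (-2.16), DZIP1 (-2.09), SLC6A15 (-2.09), LRCH2 (-2.08), TMCO1 (-2.08) and DSC3 (-2.05). Single hairpins did not pass for PLS3 (miR1 -1.52, adjusted p = 0.0757) and SLC6A15 (miR2 -1.77, adjusted p = 0.052). None of these 12 passed against control tumours 2 and 5 alone, where their changes lay between -0.62 (HSPA4L) and 0.26 (SLC6A15), and in each gene control tumours 1, 3, 4 and 6 were above control tumours 2 and 5. LIN28B, which blocks maturation of the let-7 microRNAs, changed by -1.33 ± 0.31 (SE), adjusted p = 0.00611. Its signal was 3.98 to 4.90 in control tumours 1, 3, 4 and 6, 2.24 and 2.31 in control tumours 2 and 5, and 2.16 to 2.41 with knockdown. Its change against tumours 2 and 5 was 0.033. The values in tumours 2 and 5 and with knockdown lay below the lower quartile of every array (3.72 to 4.04). Whether they exceed background is not known, which limits the size given for the fall. The same holds for OTOGL in the controls (2.68 to 2.80). ZEB1, a repressor of epithelial genes, changed by -0.92 ± 0.23 (SE), adjusted p = 0.0103, and by 0.10 (adjusted p = 0.975) against tumours 2 and 5. CD44, a hyaluronan receptor used as a stem cell marker, rose by 0.75 ± 0.16 (SE), adjusted p = 0.00492, and its change against tumours 2 and 5 was 0.087 (adjusted p = 0.987). SOX2 rose by 0.43 (adjusted p = 0.0143) and did not pass against tumours 2 and 5 (0.27, adjusted p = 0.828). Of the SHP2 partners and ERBB genes of the fixed panel, ERBB2 (0.23), ERBB3 (0.27), EGFR (0.25), GAB1 (-0.098), GAB2 (0.091) and the related phosphatase PTPN6 (0.31) did not pass, with adjusted p from 0.0794 to 0.471. With the set as a block 3 of these passed, ERBB2 (0.29, adjusted p = 0.017), ERBB3 (0.34, adjusted p = 0.0191) and PTPN6 (0.38, adjusted p = 0.0126), so that these calls depend on the model. PTPN6 also passed with quantile normalization (0.39, adjusted p = 0.0223). With array weights ERBB2 (0.30, adjusted p = 0.0249), ERBB3 (0.34, adjusted p = 0.0268), EGFR (0.36, adjusted p = 0.0432) and PTPN6 (0.44, adjusted p = 0.0054) passed. CCND1 did not pass either (-0.18, adjusted p = 0.182). With the score of host cell markers as a covariate, CD44, SOX2, LIN28B, ZEB1 and the 12 largest falls except HSPA4L no longer passed. In the smaller fit of set B alone, 10 of the 12 largest falls (all but IRS4 and HSPA4L; adjusted p from 0.0512 to 0.0715) did not pass, nor did OTOGL (1.17, adjusted p = 0.0506), CD44 (0.78, adjusted p = 0.0568), SOX2 (0.48, adjusted p = 0.0932), LIN28B (-1.45, adjusted p = 0.0649) and ZEB1 (-0.86, adjusted p = 0.123).

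Several other lists fixed before the data were examined moved in the same comparison. In the interferon response list, 15 rose, 1 fell and 18 did not pass over all genes tested (18 and 1 adjusted over the list alone) (mean 0.26, camera adjusted p = 1.25e-06, adjusted p = 0.102 with an estimated correlation); IFI6 had 0.97 and the antiviral enzyme gene OAS1 0.58, and the list mean against control tumours 2 and 5 was 0.18 (adjusted p = 4.24e-06). Of 19 p53 targets, 2 rose, 11 fell and 6 did not pass over all genes tested (2 and 11 adjusted over the list alone), with the death receptor TNFRSF10B at -1.09 (mean -0.32, camera adjusted p = 0.000236, adjusted p = 0.135 with an estimated correlation; with tumours 2 and 5 -0.12, adjusted p = 0.0239). Genes of the unfolded protein and amino acid response fell in 7 of 22 cases and rose in 0 (7 and 0 adjusted over the list alone), among them the serine synthesis enzymes PSAT1 (-0.87) and PHGDH (-0.86) (mean -0.23, camera adjusted p = 0.00097, adjusted p = 0.102 with an estimated correlation). The luminal epithelial list was higher (mean 0.21, camera adjusted p = 0.00935, adjusted p = 0.486 with an estimated correlation), with 6 of 20 members rising over all genes tested and 6 adjusted over the list alone, the oestrogen receptor gene ESR1 (0.84, and 0.72 with adjusted p = 0.094 against tumours 2 and 5) and GATA3 (0.62) among them. Its mean was -0.019 (adjusted p = 0.526) against tumours 2 and 5. The ERBB list (0.14, adjusted p = 0.0313, 0.469 as the adjusted p with an estimated correlation) and the 17q12 amplicon (0.14, adjusted p = 0.0158, 0.481 as the adjusted p with an estimated correlation) were also higher, and neither passed against tumours 2 and 5 (0.028 and -0.095). ERBB4 was the ERBB member with the smallest p (0.70, adjusted p = 2.31e-05; 0.73, adjusted p = 0.00398 against tumours 2 and 5). The inflammatory cytokine list was higher (mean 0.18, camera adjusted p = 0.00418, adjusted p = 0.343 with an estimated correlation), oxidative phosphorylation lower (mean -0.18, camera adjusted p = 0.000871, adjusted p = 0.453 with an estimated correlation) and so were the hypoxia list (mean -0.18, camera adjusted p = 0.0231, adjusted p = 0.486 with an estimated correlation) and the cholesterol and fatty acid list (mean -0.14, camera adjusted p = 0.0352, adjusted p = 0.486 with an estimated correlation).

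Markers of host cells moved with the same comparison. The host is mouse and the array is human, so these probes can read host cells only where mouse transcripts hybridise to them. The macrophage list had a mean of 0.25 (camera adjusted p = 0.000155), skeletal muscle 0.49 (0.00044), lymphocytes 0.17 (0.0199), endothelium 0.13 (0.0158), adipocytes 0.11 (0.0472) and fibroblast matrix 0.056 (0.0452). Each of these 6 calls was lost with an estimated correlation (adjusted p from 0.453 to 0.481). Blood cells did not pass (0.14, adjusted p = 0.0768). LYZ (0.68), PTPRC (0.39) and COL1A2 (0.59) rose, whereas COL5A2 fell (-0.81). The lists that did not pass were immediate-early and dissection stress genes (0.0063), oestrogen receptor response (-0.12), basal and myoepithelial (0.052), epithelial-mesenchymal transition (-0.091), stem and progenitor genes (-0.14), mammary secretory differentiation (-0.067), FOXO targets (-0.11) and antigen presentation (0.085), with adjusted p from 0.0927 to 0.927. Single members of them did change, as in MGP (-1.14), GREB1 (-1.40) and the pyruvate dehydrogenase kinase PDK4 (-0.93). The oxidative phosphorylation (-0.038), cholesterol (-0.012), endothelial (0.022), adipocyte (0.055) and lymphocyte (0.021) lists did not pass against control tumours 2 and 5, with adjusted p from 0.38 to 0.785. The unfolded protein (-0.15), inflammatory cytokine (0.090), hypoxia (-0.17), macrophage (0.099), skeletal muscle (0.40) and fibroblast (0.065) lists kept their call there, with adjusted p from 0.000287 to 0.0319. With quantile normalization the hypoxia (-0.15), cholesterol (-0.086), fibroblast (0.042), endothelial (0.084), adipocyte (0.095) and lymphocyte (0.11) calls were lost (adjusted p from 0.0615 to 0.261), as they were with cyclic loess (from 0.0856 to 0.423). With the set as a block the cholesterol (-0.10), fibroblast (0.042), adipocyte (0.084) and lymphocyte (0.12) calls were lost (adjusted p from 0.062 to 0.156). In all, 19 of 28 lists passed, 11 higher and 8 lower, 0 with an estimated correlation and 11 with control tumours 2 and 5 alone. In 1 list, mammary secretory differentiation, the median (0.092) and the test pointed up and the mean down.

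Over all genes tested, 3414 of 18377 passed in the mean of both hairpins, 1015 higher and 2399 lower, while 479 passed with each hairpin in the same direction. On values centred at each array's median, 1515 were higher and 1999 lower. With array weights there were 3121 higher and 3926 lower. Changes of over 1 log2 unit were 19 rises and 153 falls. With control tumours 2 and 5 alone, 138 genes passed, 50 higher and 88 lower. Of the calls, 110 were shared in the same direction, and of the 153 falls 16 also passed, among them GREB1, MYC, TNFRSF10B and SLC6A14. In GREB1, MYC and SLC6A14 miR2 carried the mean. With the set as a block their changes were 0.33, -0.24 and 0.54 with miR1 and -2.95, -2.32 and -3.84 with miR2. Within set B 306 genes passed, and 4101 with the set as a block. With the host score as a covariate 591 passed, 371 higher and 220 lower, and with the hairpins weighted by their number of tumours 2064. Leaving out single tumours moved the count to 2155 (control 1), 2086 (control 3), 2188 (control 6), 2214 (miR2 tumour 3) and 5706 (control 5).

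With SHP2 miR1 alone, the question is which of these changes hold for a single hairpin. MUC19 (1.98 ± 0.25 (SE), adjusted p = 0.000381) and GLYATL2, a glycine acyltransferase (1.76 ± 0.17 (SE), adjusted p = 1.88e-05), had the largest rises. They were followed by the progesterone receptor PGR (1.06), CD44 (1.04), the neuropeptide receptor NPY1R (0.99) and the kinase NRK (0.94). Against control tumours 2 and 5, GLYATL2 kept its call (1.68, adjusted p = 0.00543), and MUC19 (1.71, adjusted p = 0.0825), PGR (0.96, adjusted p = 0.117), CD44 (0.38), NPY1R (0.66) and NRK (0.60) did not pass. The largest falls were HOXD10 (-2.76), RADX (-2.75), IRS4 (-2.73), SLC6A15 (-2.41), SMARCA1 (-2.38) and ECHDC1 (-2.31), and against tumours 2 and 5 these lay between -0.22 and 0.065 with none passing. MYC had -0.23 (adjusted p = 0.382) and DUSP6 -0.37 (adjusted p = 0.126), and neither passed. With array weights MYC did pass (-0.36, adjusted p = 0.0304). SPRY4 (-0.51, adjusted p = 0.0177), ETV4 (-0.60), ETV5 (-0.65) and the ephrin receptor EPHA4 (-0.49) fell, and ESR1 rose (0.58, adjusted p = 0.0263). None of these 5 passed against tumours 2 and 5, where the values were -0.44, -0.59, -0.55, -0.52 and 0.45. LIN28B (-1.37, adjusted p = 0.0198) and ZEB1 (lower by a fold of 2.01, adjusted p = 0.0216) fell against all controls but had -0.0021 and 0.016 against tumours 2 and 5.

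In the ERK output list, 0 rose, 5 fell and 13 did not pass over all genes tested (0 and 8 adjusted over the list alone) with miR1 (mean -0.23, camera adjusted p = 0.00013, adjusted p = 0.233 with an estimated correlation). The mean was -0.27 (adjusted p = 1.59e-07) with control tumours 2 and 5, -0.28 within set A and -0.19 within set B. Luminal epithelial genes were higher, 2 of 20 over all genes tested and 10 adjusted over the list alone (mean 0.27, camera adjusted p = 5.89e-07, adjusted p = 0.418 with an estimated correlation), with ELF3 at 0.51. Oestrogen receptor response genes were also higher, 3 of 20 and 7 adjusted over the list alone (mean 0.26, camera adjusted p = 1.07e-06, adjusted p = 0.233 with an estimated correlation), with MYB at 0.32 and PKIB at 0.37. The same direction was called for the 17q12 amplicon (mean 0.18, camera adjusted p = 0.000556, adjusted p = 0.495 with an estimated correlation), the ERBB list (mean 0.16, camera adjusted p = 0.00442, adjusted p = 0.418 with an estimated correlation) and skeletal muscle (mean 0.39, camera adjusted p = 0.000556, adjusted p = 0.603 with an estimated correlation). The p53 targets were lower (mean -0.23, camera adjusted p = 0.000173, adjusted p = 0.233 with an estimated correlation), with the death receptor FAS at -1.04. Cell cycle genes had a mean of -0.10 (adjusted p = 0.0198, 0.812 as the adjusted p with an estimated correlation), with 0 of 35 members passing; within set A and set B the means were -0.11 (adjusted p = 0.0131) and -0.087 (adjusted p = 0.079). Against control tumours 2 and 5, that mean turned to 0.21 (camera adjusted p = 1.59e-07), and the luminal (0.042), oestrogen (0.11), amplicon (-0.058), ERBB (0.047) and p53 (-0.031) lists did not pass (adjusted p from 0.0731 to 0.603). These values rest on the preset correlation, since the estimated correlation was not run for tumours 2 and 5 alone. Of the 8 lists called, ERK output and skeletal muscle (0.31, adjusted p = 0.0156) kept their call and direction there. The other 20 lists did not pass against all controls, MYC targets (-0.083, adjusted p = 0.061; 0.13, adjusted p = 0.000502 against tumours 2 and 5) and the interferon response (0.083, adjusted p = 0.061) among them. The median and the mean differed in sign in 3 of them (secretory differentiation -0.013 and 0.0086, antigen presentation 0.0093 and -0.087, adipocytes 0.024 and -0.023).

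In total 874 genes passed with miR1, 253 higher and 621 lower, or 392 and 522 on median-centred values. With the set as a block 1225 passed, 492 higher and 733 lower, and with array weights 3371. The host score as a covariate gave 1243, 553 higher and 690 lower. Within set A 10 genes passed, namely PTPN11, PRKAA2, ABCC4, ETV4, CYBRD1, MAP3K5 and TUSC3 lower and GLYATL2, PGR and TUBAL3 higher; within set B PTPN11 alone did. Of these, PRKAA2, ABCC4, CYBRD1, MAP3K5, TUSC3 and TUBAL3 are named after their values were seen. With control tumours 2 and 5 alone, 25 passed, 13 of them shared with the 874 in the same direction. Leaving out 1 control gave 382, 1913, 233, 273, 1766 and 262 genes for control tumours 1 to 6, and leaving out miR1 tumour 1, 2, 3 or 4 gave a count that was 62.2%, 65.0%, 62.9% or 59.4% as large as 874, counting any gene that passed.

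The miR2 tumours differed more from the controls. CBLN2, a synapse organiser (3.11 ± 0.20 (SE), adjusted p = 7.0e-09), and the membrane peptidase MME (2.98 ± 0.20 (SE), adjusted p = 8.73e-09) rose most, followed by VSTM2A (2.42), LINC00417 (2.42), PPFIA2 (2.40) and SYT1 (2.37). The amino acid transporter SLC6A14 fell most (-3.76 ± 0.14 (SE), adjusted p = 1.18e-12), and the 6 largest falls also held IRS4, GREB1, an oestrogen receptor target (-3.16 ± 0.21 (SE), adjusted p = 8.73e-09), PLS3, HOXD10 and the vitamin B12 binding protein TCN1 (-2.84). The 6 rises and SLC6A14, GREB1 and TCN1 passed against control tumours 2 and 5 too, with changes such as 2.76 for CBLN2, -3.82 for SLC6A14 and -3.62 for GREB1. IRS4 (-3.17) and HOXD10 (-2.88) fell against all controls but had -0.41 and -0.35 against tumours 2 and 5 without passing, and PLS3 went from -2.88 to -0.74 (adjusted p = 0.0266). PGR fell by 2.43 ± 0.18 (SE, adjusted p = 3.12e-08), and TFF1 had -0.98. MYC fell by 2.37 ± 0.17 (SE, adjusted p = 1.88e-08), to 4.73 to 5.28 against 6.99 to 7.75 in the controls, and by 1.97 against tumours 2 and 5. DUSP6 (-1.58 ± 0.17 (SE), adjusted p = 3.63e-06), SPRY4 (-1.15), ETV4 (-0.99) and CCND1 (-0.45, adjusted p = 0.0127) fell, and passed against tumours 2 and 5 as well. The CCND1 call was lost with quantile normalization (-0.29, adjusted p = 0.122), cyclic loess (-0.26, adjusted p = 0.165) and the host score (-0.61, adjusted p = 0.0561). ESR1 rose (1.11, adjusted p = 0.00033; 0.98 against tumours 2 and 5), as did GATA3 (1.01) and MUC1 (1.71). LIN28B (-1.30) and ZEB1 (-0.83) fell against all controls, and had 0.068 and 0.19 against tumours 2 and 5. With the set as a block ZEB1 did not pass (-0.86, adjusted p = 0.0739), whereas ERBB2 (0.41, adjusted p = 0.0146), ERBB3 (0.39, adjusted p = 0.0429) and PTPN6 (0.56, adjusted p = 0.00708) did, which without it had adjusted p of 0.129, 0.312 and 0.0615.

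Growth genes fell together with miR2. Of 35 cell cycle genes, 0 rose, 33 fell and 2 did not pass over all genes tested (0 and 33 adjusted over the list alone) (mean -0.83, camera adjusted p = 1.47e-17, adjusted p = 0.194 with an estimated correlation), with KIF2C at -1.25, the replicative helicase gene MCM6 at -1.12 and BIRC5 at -0.99. Of 32 MYC targets, 0 rose, 31 fell and 1 did not pass over all genes tested (0 and 32 adjusted over the list alone) (mean -0.74, camera adjusted p = 6.57e-17, adjusted p = 0.0808 with an estimated correlation), with POLR1B at -1.12 and RRS1 at -0.98. Against control tumours 2 and 5 the means were -0.52 and -0.52, and within set B -0.82 and -0.69. Oestrogen receptor response genes fell in 10 of 20 cases and rose in 0, with the same counts adjusted over the list alone (mean -0.50, camera adjusted p = 0.0023, adjusted p = 0.317 with an estimated correlation). In the ERK output list, 1 rose, 8 fell and 9 did not pass over all genes tested (2 and 11 adjusted over the list alone) (mean -0.39, camera adjusted p = 0.00323, adjusted p = 0.293 with an estimated correlation). Genes of the unfolded protein and amino acid response fell in 9 of 22 cases, or 10 adjusted over the list alone (mean -0.42, camera adjusted p = 0.000199, adjusted p = 0.0699 with an estimated correlation), with PSAT1 at -1.51, the asparagine synthetase gene ASNS at -0.86 and the cystine transporter SLC7A11 at -1.49. The p53 targets (mean -0.42, camera adjusted p = 0.0023, adjusted p = 0.194 with an estimated correlation), oxidative phosphorylation (mean -0.32, camera adjusted p = 0.000182, adjusted p = 0.317 with an estimated correlation), hypoxia (mean -0.31, camera adjusted p = 0.0154, adjusted p = 0.473 with an estimated correlation) and cholesterol (mean -0.26, camera adjusted p = 0.00994, adjusted p = 0.454 with an estimated correlation) lists were lower too. In the interferon list, 20 rose, 2 fell and 12 did not pass over all genes tested (23 and 2 adjusted over the list alone) (mean 0.43, camera adjusted p = 2.54e-07, adjusted p = 0.0734 with an estimated correlation), with IFI6 at 1.76 and OAS1 at 1.08. Antigen presentation (mean 0.26, camera adjusted p = 0.00958, adjusted p = 0.0808 with an estimated correlation) and inflammatory cytokines (mean 0.33, camera adjusted p = 0.000426, adjusted p = 0.194 with an estimated correlation) were higher, with the beta-2 microglobulin gene B2M at 0.45 and IL6 at 1.09.

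Host cell lists rose beside these groups with miR2. The score of the fibroblast, endothelial and macrophage lists was highest in the compressed miR2 tumours 1 and 3 (1.31 and 0.96). In miR2 tumour 2 it was 0.19, below miR1 tumour 7 (0.32) and control tumour 5 (0.49). More host cells and the compression cannot be told apart by these values. The macrophage list had a mean of 0.43 (camera adjusted p = 9.33e-06), skeletal muscle 0.58 (0.00323), lymphocytes 0.32 (0.00323), blood cells 0.28 (0.0231), adipocytes 0.25 (0.0128), endothelium 0.23 (0.00323) and fibroblast matrix 0.11 (0.0269), and each call was lost with an estimated correlation (adjusted p from 0.315 to 0.473). The intensity compression of miR2 tumours 1 and 3 moved with the same contrast. The median change was 0.24 for the genes in the third decile of mean signal and -0.20 for those in the ninth. Cyclic loess, which removes such a trend, left the cell cycle, MYC, oestrogen, unfolded protein and interferon lists called with miR2 (means -0.67, -0.58, -0.41, -0.34 and 0.32), but not hypoxia (-0.25, adjusted p = 0.063), cholesterol (-0.13, 0.383), fibroblast (0.030, 0.113), endothelial (0.078, 0.137), adipocyte (0.14, 0.063), lymphocyte (0.16, 0.0507) or blood cell (0.079, 0.349) genes. Of the 28 lists, 19 passed with miR2, 0 with an estimated correlation and 17 with control tumours 2 and 5 alone, where cholesterol (-0.13, adjusted p = 0.186) and blood cell genes (0.17, adjusted p = 0.0787) did not pass. The means there were -0.43 for ERK output, -0.65 for the oestrogen response, -0.33 for the unfolded protein list, -0.22 for p53 targets, -0.17 for oxidative phosphorylation, -0.29 for hypoxia, 0.36 for interferon, 0.27 for antigen presentation, 0.25 for cytokines, 0.29 for macrophages, 0.49 for skeletal muscle, 0.17 for lymphocytes, 0.19 for adipocytes, 0.13 for endothelium and 0.12 for fibroblasts (adjusted p from 4.14e-08 to 0.036). With the set as a block the cholesterol call was lost (-0.17, adjusted p = 0.0836). The median and the mean differed in sign in 4 lists that did not pass (luminal -0.062 and 0.14, basal 0.068 and -0.016, epithelial-mesenchymal -0.0036 and 0.029, secretory 0.15 and -0.14). Over all genes 5508 passed, 2163 higher and 3345 lower. On median-centred values there were 2824 higher and 3035 lower, and without the third of genes with the lowest mean 1300 and 3216, so that the excess of falls depends on scaling and filter. There were 803 against tumours 2 and 5, of which 716 were shared in the same direction, 2550 within set B and 4578 with the set as a block. With array weights there were 8868. With the host score as a covariate 602 passed, and with the CTRL miR and miR2 arrays alone 3366. Leaving out miR2 tumour 1 or 3 gave 2935 or 2391.

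Both hairpins were compared with the same 6 control tumours. Among the genes that passed with each, 479 moved in the same direction, 89 up and 390 down, and 26 in opposite directions. Independent lists of these lengths would share 29.8 rises and 113 falls. Unchanged groups simulated against the same simulated controls shared a mean of 0.01 and at most 1 gene in 100 simulations. All values there, controls included, were drawn as independent noise for each gene. The simulations therefore lack the difference of control tumours 1, 3, 4 and 6 and the array sets. They cannot show how many shared calls these would give. With the controls divided between the hairpins, 3 each, the shared count was between 9 and 181 with a median of 49 over 20 divisions. The rises with the largest smaller change were MUC19, CDHR3 (0.79 and 0.78), GLYATL2, NPY1R, RPS6P6 (0.72 and 0.74) and FAM83B, and the falls were HOXD10, RADX, IRS4, SMARCA1, ECHDC1 and LRCH2 (-2.08 and -2.09). Against control tumours 2 and 5 alone, 15 genes were shared and 2 went opposite ways, and of those 12 named genes none passed with each hairpin. PTPN11, COL5A2 and, named after their values were seen, CPS1, TUSC3 and SCGB2A2 were among the 15, as was ERBB4 with a rise of 0.67 (miR1) and 0.80 (miR2). Of the 15, 5 also passed with each hairpin against all 6 controls (PTPN11, COL5A2, CPS1, TUSC3 and ERBB4) and 10 did not. SCGB2A2 had an adjusted p of 0.717 with miR1 there, and KLK2 and KLK3, which also belong to the 10 and are named after their values were seen, were higher in control tumours 2 and 5 than in all other arrays. Without control tumour 1, 3, 4 or 6 the shared count was 185, 133, 157 or 146, and without tumour 2 or 5 it was 1138 or 1246. Without miR1 tumour 4 or miR2 tumour 1 or 3 it was 306, 263 or 249.

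The hairpins were compared directly, which does not involve the control tumours except through the estimate of the spread. SLC6A14 differed by 4.28 ± 0.14 (SE), adjusted p = 6.06e-14, GREB1 by 3.52 ± 0.20 (SE), adjusted p = 8.09e-10 and PGR by 3.49 ± 0.18 (SE), adjusted p = 1.38e-10, followed by TCN1 (3.36), CYP2B7P (3.18) and the RAC exchange factor PREX1 (3.05). MME (-4.03 ± 0.19 (SE), adjusted p = 7.16e-11), CBLN2 (-3.16), LINC00417 (-2.46), PPFIA2 (-2.40), the cadherin CDH8 (-2.37) and ANKRD20A11P (-2.32) were lower with miR1. PGR was 8.04 to 8.52 in the controls, 9.10 to 9.51 with miR1 and 5.26 to 6.51 with miR2, so that it lay above the controls in 7 of 7 miR1 tumours and below them in 3 of 3 miR2 tumours. MYC was 2.14 ± 0.17 (SE) higher with miR1 (adjusted p = 5.08e-08), DUSP6 1.22 (adjusted p = 5.46e-05), SPRY4 0.64 (adjusted p = 0.0050) and CCND1 0.53 (adjusted p = 0.00553), and ESR1 was -0.53 (adjusted p = 0.0401). Within set B, where 3 miR1 and 3 miR2 tumours lie, the differences were 2.05 for MYC (adjusted p = 0.000186), 3.45 for PGR, 1.06 for DUSP6, 0.50 for SPRY4 (adjusted p = 0.0797) and 0.45 for CCND1 (adjusted p = 0.064). The CCND1 difference was also lost with quantile normalization (0.35, adjusted p = 0.0805) and cyclic loess (0.31, adjusted p = 0.126). The ESR1 difference was lost with array weights (-0.42, adjusted p = 0.0627), and the SPRY4 difference with the host score as a covariate (0.37, adjusted p = 0.314).

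Of 35 cell cycle genes 32 were higher with miR1 and 0 lower, with the same count adjusted over the list alone (mean 0.73, camera adjusted p = 6.44e-17, adjusted p = 0.179 with an estimated correlation), and of 32 MYC targets 29 were higher, or 32 adjusted over the list alone (mean 0.66, camera adjusted p = 9.8e-17, adjusted p = 0.0734 with an estimated correlation). Oestrogen receptor response genes were higher in 11 of 20 cases, or 12 adjusted over the list alone (mean 0.76, camera adjusted p = 3.13e-08, adjusted p = 0.0734 with an estimated correlation), with TFF1 at 1.21 and STC2 at 0.93. The unfolded protein and amino acid list was higher (7 of 22 in both counts; mean 0.37, camera adjusted p = 0.000177), and antigen presentation lower (5 of 11, 6 adjusted over the list alone; mean -0.34, adjusted p = 0.00067). These 2 calls held with an estimated correlation (adjusted p = 0.0334 for each), and no other list call of any comparison did. Interferon response (mean -0.35, camera adjusted p = 1.63e-06, adjusted p = 0.0734 with an estimated correlation) and inflammatory cytokine genes (mean -0.31, camera adjusted p = 0.00036, adjusted p = 0.179 with an estimated correlation) were lower with miR1, as were macrophage (-0.37), lymphocyte (-0.30), adipocyte (-0.27), endothelial (-0.21) and blood cell (-0.26) markers (camera adjusted p from 1.21e-05 to 0.0199, and from 0.301 to 0.417 with an estimated correlation). Epithelial-mesenchymal transition genes were lower (mean -0.24, camera adjusted p = 0.0227, adjusted p = 0.179 with an estimated correlation), with TWIST1 at -0.75 and ZEB2 at -1.10. Oxidative phosphorylation (mean 0.27, camera adjusted p = 0.000365, adjusted p = 0.357 with an estimated correlation), hypoxia (mean 0.25, camera adjusted p = 0.0404, adjusted p = 0.556 with an estimated correlation) and cholesterol genes (mean 0.24, camera adjusted p = 0.00913, adjusted p = 0.417 with an estimated correlation) were higher. The ERK output list did not differ by the test (0.17, adjusted p = 0.184). With cyclic loess the cholesterol, hypoxia, oxidative phosphorylation, epithelial-mesenchymal, endothelial, adipocyte, lymphocyte and blood cell calls were lost (adjusted p from 0.0607 to 0.525), and with the set as a block the cholesterol call (0.13, adjusted p = 0.086). The luminal list did not pass (0.12, adjusted p = 0.129), with 9 of 20 members higher and 3 lower over all genes tested (9 and 4 adjusted over the list alone), KRT18 higher (0.49) and GATA3 (-0.78) and MUC1 (-1.20) lower with miR1.

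The median and the mean differed in sign in 3 lists that did not pass (ERBB -0.020 and 0.036, stem -0.079 and 0.012, secretory -0.12 and 0.15). In all 16 of 28 lists and 4136 of 18377 genes passed between the hairpins, 2626 higher and 1510 lower with miR1. With the set as a block 2523 genes passed, 1904 higher and 619 lower, and within set B 972 did. Cyclic loess left 2302 calls. With the host score as a covariate 654 passed. Leaving out miR2 tumour 1 or 3 gave 1659 or 1310 genes.

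**Figure D2:**
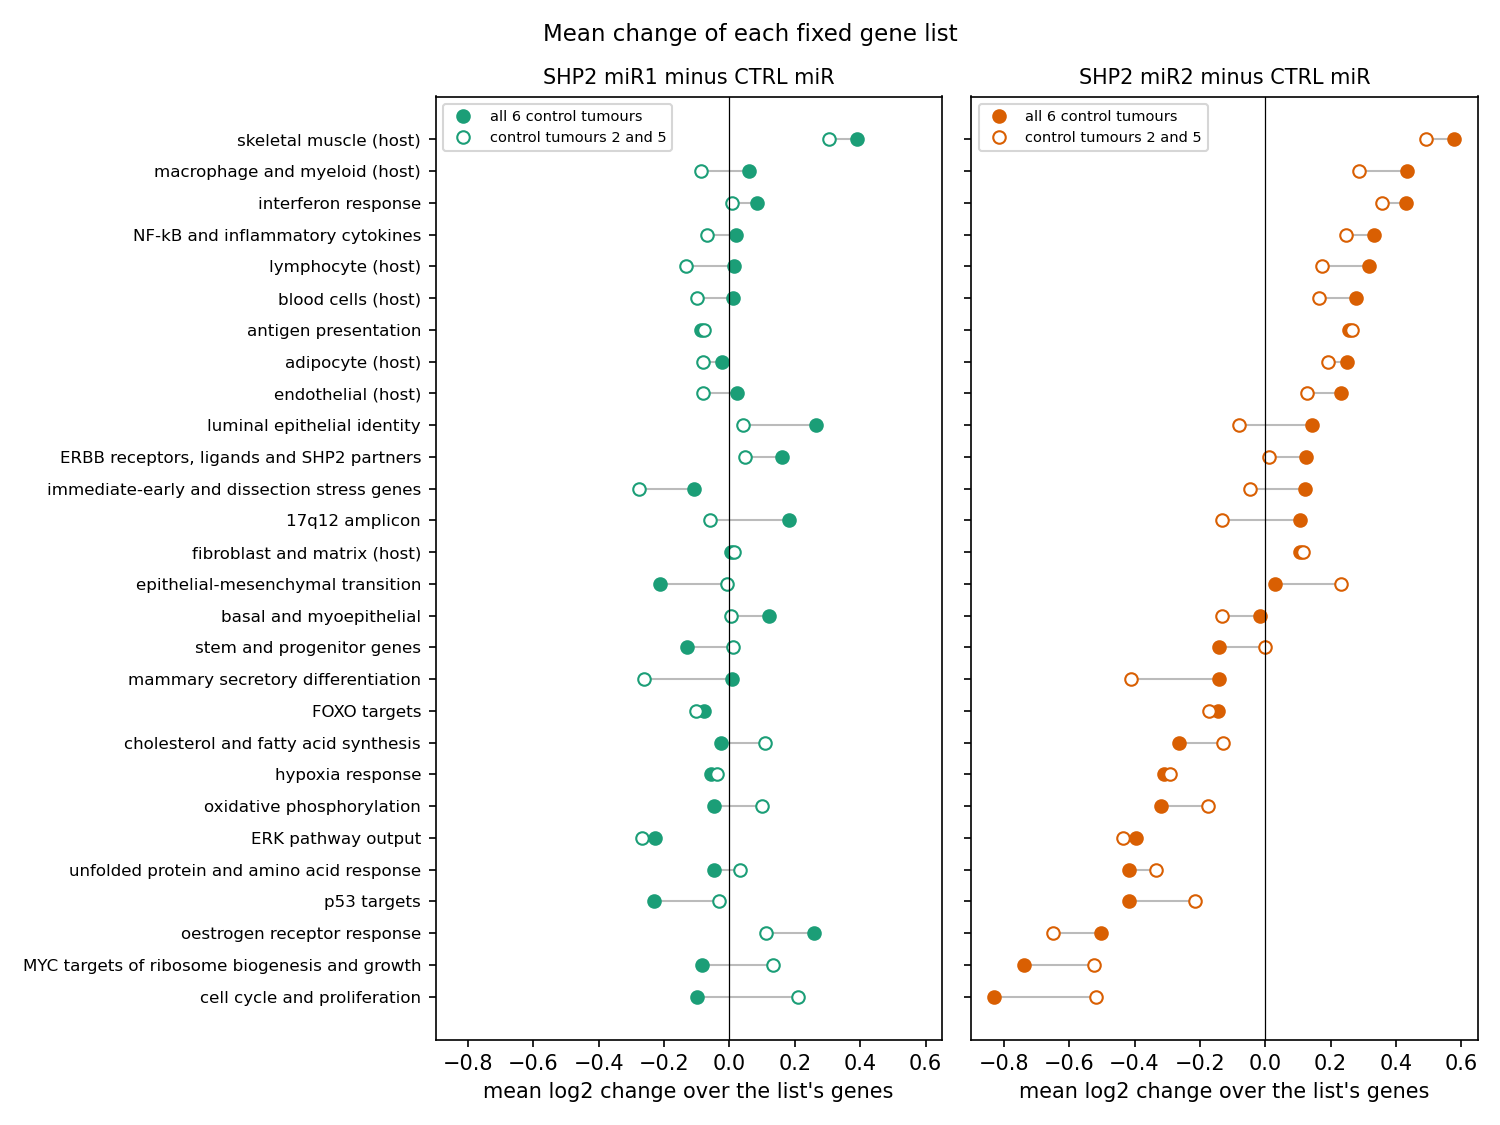
Mean log2 change over the members of each of the 28 gene lists with miR1 (left) and miR2 (right), as filled points against all 6 control tumours and open points against control tumours 2 and 5. Cell cycle genes lie at -0.10 and 0.21 with miR1 and at -0.83 and -0.52 with miR2, and ERK output genes are lower in each case (-0.23, -0.27, -0.39 and -0.43).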

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

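Among the 56 named genes (list members aside) and the means of the 28 lists, each in the CTRL miR and the SHP2 miR1 group, 4 of 168 sets of values held 1 tumour far from the rest of its group, where chance gives 8.4. GLYATL2 had a log2 signal of 4.19 in control tumour 5, against 3.94 in the nearest other control. CD44 had 6.75 in miR1 tumour 5 (nearest 6.97), NPY1R had 5.53 in miR1 tumour 2 (nearest 6.03) and CDH8 had 3.85 in miR1 tumour 1 (nearest 4.16). No tumour held more than 1 of these values. The miR2 group has 3 tumours and was not examined in this way. No explanation was tested for these values. The 8.4 holds for independent, normally distributed values, whereas both groups span the array sets and 4 controls stood apart. Such structure can hide a single outlier, so the low number does not show that outliers are rare.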

How the results depend on the processing

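The alternatives with control tumours 2 and 5 alone, array sets, kidney line marker scores and cyclic loess were chosen after seeing the data. The cause was not tested for any value in these paragraphs unless stated. PTPN11 kept its direction and its call with miR1 and with miR2 under each alternative run. Leaving out single tumours gave -1.51 to -1.42 with miR1 and -1.97 to -1.88 with miR2. The counts of genes without 1 tumour were 2086 to 5706 for both miRs (3414 with all tumours), 233 to 1913 for miR1 (874), 2391 to 7739 for miR2 (5508), 1310 to 5923 between the miRs (4136) and 133 to 1246 for genes shared by the miRs (479). The lowest values came without control tumour 3 (both, miR1, shared) or miR2 tumour 3 (miR2, between the miRs). The highest came without control tumour 5 (both, miR2, shared), control tumour 2 (miR1) or miR2 tumour 2 (between the miRs).

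Array weights gave 7047 genes for both miRs, 3371 for miR1, 8868 for miR2, 7180 between the miRs and 2099 shared. The host score as a covariate gave 591 for both, 602 for miR2, 654 between the miRs and 117 shared, but 1243 for miR1. Weighting the miRs by number of tumours gave 2064 for both. Only the groups compared gave 3366 for miR2, with fewer arrays in the fit. Controls divided between the miRs gave a median of 49 shared genes, with 3 controls per miR. Control tumours 2 and 5 alone, a fit with fewer tumours, gave 138, 25 and 803 for both, miR1 and miR2, and 15 shared. The kidney score gave 162, 33, 1375 and 22, and with the set as a block 256, 49, 1705 and 35. Set A alone gave 10 for miR1. Set B alone gave 306, 1, 2550, 972 between the miRs and 1 shared, again with fewer tumours. Between the miRs, the set as a block gave 2523 and cyclic loess 2302. Quantile normalization, median centring, the low-value filter, all clusters and the trended prior moved each of these counts by a factor of at most 1.5, the limit set for a change. The largest of these moves were 874 to 603 with miR1 and 479 to 331 shared (low-value filter), 4136 to 2990 between the miRs (quantile normalization) and 5508 to 7153 with miR2 and 3414 to 4268 for both miRs (all clusters).

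Tumours of different groups share replicate numbers, but the labels do not say that a number marks an animal or a day. Of 6 pairs of a CTRL miR and an SHP2 miR1 tumour with the same number, 5 had a correlation over 0.1 (0.21 to 0.37) and the other had -0.30, and 3 of the 6 correlated best with their own number. None of the other 6 pairs, which hold an miR2 tumour, had a correlation over 0.1 (-0.42 to 0.022). The 5 pairs with such a correlation each lay within 1 array set. The pair at -0.30 and the 6 pairs with an miR2 tumour each joined set A with set B. The correlations thus follow the array sets, and the numbers were not taken to pair the tumours. With the replicate number as a block, 3881, 745, 7255 and 6773 genes passed for both, miR1, miR2 and between the miRs, 382 were shared, and PTPN11 had -1.49 and -1.89. The block ended the ESR1 call between the miRs (-0.39, adjusted p = 0.0915).

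Results that turned in direction, by mean or by the sign of the test, came under 4 alternatives, and the cause was not tested. The host score gave list means of cholesterol and fatty acid synthesis 0.012 (both), 0.0042 (miR2) and 0.016 (miR1 against miR2), endothelial (host) -0.049 (both), -0.072 (miR2) and 0.044 (miR1 against miR2), adipocyte (host) -0.040 (both) and lymphocyte (host) -0.056 (both) and -0.061 (miR2). Control tumours 2 and 5 alone gave list means of 17q12 amplicon -0.095 (both) and -0.058 (miR1), luminal epithelial identity -0.019 (both), cholesterol and fatty acid synthesis -0.012 (both) and cell cycle and proliferation 0.21 (miR1). For genes they gave SMARCA1 0.0044 (both) and 0.065 (miR1), SLC6A15 0.26 (both), IRS4 0.028 (miR1), LRCH2 0.0021 (miR1), ZEB1 0.10 (both), 0.016 (miR1) and 0.19 (miR2) and LIN28B 0.033 (both) and 0.068 (miR2). The kidney score gave list means of 17q12 amplicon -0.10 (both) and -0.075 (miR1), luminal epithelial identity -0.033 (both) and cell cycle and proliferation 0.18 (miR1). For genes it gave SLC6A15 0.20 (both), IRS4 0.095 (miR1), SMARCA1 0.062 (miR1), LRCH2 0.018 (miR1), ZEB1 0.089 (both), 0.040 (miR1) and 0.14 (miR2) and LIN28B 0.011 (both) and 0.028 (miR1). The kidney score with the set as a block gave list means of 17q12 amplicon -0.067 (both) and -0.087 (miR1), luminal epithelial identity 0.0056 (both), cholesterol and fatty acid synthesis 0.0021 (both) and cell cycle and proliferation 0.18 (miR1). For genes it gave SLC6A15 0.18 (both), IRS4 0.085 (miR1), SMARCA1 0.065 (miR1), LRCH2 0.017 (miR1), ZEB1 0.077 (both), 0.044 (miR1) and 0.11 (miR2) and LIN28B 0.0048 (both) and 0.030 (miR1). IRS4 and LIN28B belong to the marker list behind the kidney score, and the endothelial list to the host score, so their change follows in part from how the scores were built. Cell cycle genes with miR1 passed the threshold in the opposite direction under 3 alternatives, with camera adjusted p = 1.59e-07 (tumours 2 and 5), 3.94e-06 (kidney score) and 3.61e-06 (with the set as a block). These values rest on the preset correlation, and an estimated correlation was not run for these alternatives. Against all controls the call of this list was lost with an estimated correlation, so a rise is not shown by these values alone.

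For values of single named genes, control tumours 2 and 5 alone turned 10, left 81 with the same call and direction, and moved 41 below and 1 above the threshold. Quantile normalization left 126 the same, moved 3 below and 4 above. Cyclic loess left 125, with 3 below and 5 above. The host score left 102, with 31 below. Set B alone left 91, with 41 below and 1 above, in a fit with fewer tumours. The calls lost with quantile normalization were CCND1 with miR2 (-0.29, adjusted p = 0.122) and between the miRs (0.35, adjusted p = 0.0805) and GLYATL2 with miR2 (0.59, adjusted p = 0.0525). The trended prior ended those of IRS4 (-2.73, adjusted p = 0.0509) and LIN28B (-1.37, adjusted p = 0.0508) with miR1 and of ZEB1 (-0.83, adjusted p = 0.0587) and LIN28B (-1.30, adjusted p = 0.0517) with miR2. The call of ZEB1 with miR2 was also lost with all clusters (-0.83, adjusted p = 0.0576) and with the groups compared alone (-0.83, adjusted p = 0.121). Among the losses with the host score were 11 of the 12 largest falls for both miRs (all but HSPA4L, adjusted p from 0.0993 to 0.231). Their changes there lay between -2.01 (IRS4) and -1.35 (SLC6A15). CD44 (0.65), SOX2 (0.52), LIN28B (-0.87) and ZEB1 (-0.69) for both miRs were lost too, with adjusted p from 0.0544 to 0.204. Leaving out single tumours left 2053 the same, moved 59 below and 16 above, and turned 0. Of the list calls, 2 held with an estimated correlation and 60 did not, 48 held with the directional and 56 with the mixed test of fry, 46 with quantile normalization, 41 with cyclic loess, 56 with the set as a block and 32 with the host score. Among 10000 random lists matched on mean expression, the cholesterol, fibroblast, endothelial, adipocyte and lymphocyte means for both miRs lay at the percentiles 10.6, 82.4, 94.0, 88.5 and 97.0. For miR2 the cholesterol, oxidative phosphorylation, fibroblast, endothelial, adipocyte and blood cell means lay at 12.5, 2.65, 84.2, 94.3, 95.9 and 85.6, and between the miRs the hypoxia, cholesterol, oxidative phosphorylation, endothelial and blood cell means at 96.7, 76.9, 91.7, 13.6 and 18.2. The other list calls lay nearer to either end.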

Other observations

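In this part, the tests of loss of SHP2 alone, of a deeper knockdown and of the array sets and the splits within the array sets were chosen only after the result was seen, as were the alternatives with cyclic loess and with single array sets, and the genes of the next paragraph.

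Control tumours 2 and 5 differed from all other arrays in a group of genes. KLK2 had 8.10 and 7.85 in control tumours 2 and 5, 4.86 to 5.46 in the other 4 controls and 5.13 to 6.02 with knockdown. KLK3 had 7.21 and 6.91, against 4.78 to 5.07 and 5.07 to 5.67. PIP had 7.11 and 6.82, against 4.97 to 5.33 and 5.27 to 6.70. SGK1 had 7.82 and 7.91, against 6.47 to 6.80 and 5.67 to 7.19. RGS2 (6.33 and 6.58), EMP1 (6.41 and 6.56) and MYBPC1 (6.30 and 6.47) were also highest in those tumours. Against these controls alone KLK2 had -2.45 with miR1 and -2.12 with miR2, and KLK3 had -1.71 and -1.68, whereas neither passed against all 6 controls. With miR2, RGS2 (adjusted p = 0.00135), EMP1 (adjusted p = 0.000101) and SGK1 (adjusted p = 0.00376) passed against all 6 controls too, and lay below every control (4.19 to 4.53, 4.37 to 4.53 and 5.67 to 5.91).

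The 153 falls of over 1 log2 unit in the mean of both miRs were weighed against 3 explanations. They include genes that fell with miR2 alone, such as SLC6A14 (7.82 to 8.40 with miR1, 7.49 to 7.78 in the controls). For 122 of the 153 genes, control tumours 2 and 5 both lay inside or below the range of the 10 knockdown tumours. That is 79.7% (bootstrap interval over genes 73.2% to 86.3%). The interval was drawn from genes, which move together, so it does not measure the spread between tumours. Those 2 tumours keep SHP2, so the share argues against loss of SHP2 alone as the cause of most of these falls. It rests on 2 control tumours. A gene that fell with miR2 alone can count as inside the range through its miR1 tumours. Both control tumours lay above the range for 9 genes and 1 of the 2 for 22, which stay open. Cells of another human line in control tumours 1, 3, 4 and 6 are a candidate explanation: of 14 markers of a human embryonic kidney line whose values had not been looked up, 5 (INA, MEIS2, AMOT, ELAVL2 and CKB, 35.7%) were higher in each of the 4 tumours than in each of the other 12 arrays, against 8.76% of all genes (1609), with a one-sided Fisher exact p = 0.00522, where chance gives 0.0549% per gene. The 0.0549% holds for 4 tumours named in advance, whereas these 4 were picked from the profiles. The share of all genes is therefore the comparison that counts. Of the 153 falls 142 (92.8%) had that pattern, as had 17 of another 17 markers, chosen after the values were seen. Both groups of genes were chosen from these same values, so their shares are no test. The other 9 of the 14 markers lacked the pattern, and BASP1 went the other way (7.78 to 7.98 in the 4 tumours, 8.02 to 8.46 in the others). The line was not identified by other means, and a change within the BT474 cells stays open. For mouse host cells, the median of 63 fibroblast, endothelial and macrophage genes was -0.20 in those 4 tumours relative to the other 12 arrays (bootstrap interval over genes, not tumours, -0.25 to -0.13). This argues against host cells only as far as the human probes read mouse transcripts, which is not known. The other 12 arrays also hold the compressed miR2 tumours 1 and 3, where the score of these lists was highest (1.31 and 0.96).

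The 4136 differences between the miRs were weighed against 3 explanations. A deeper knockdown with miR2 to which genes respond in proportion would put the miR1 change at a share of the miR2 change near the PTPN11 ratio of 0.761 (0.686 to 0.841). Genes chosen for their difference have a low share by that choice, so genes were chosen between the miRs without 1 miR1 and 1 miR2 tumour, and the share of the mean changes was taken in those 2 tumours. Over all 21 such pairs the share was at most 0.411 against all 6 controls and at most 0.0294 against control tumours 2 and 5. It was below the PTPN11 ratio in each pair. Holding tumours out does not remove the difference between the array sets or the compression of miR2 tumours 1 and 3. With miR2 tumour 2 held out, miR1 tumours 5 to 7 of set B gave 0.41, 0.21 and 0.33 against all 6 controls. Those of set A, 1 to 4, gave -0.14, 0.090, -0.50 and -0.13. This test can therefore not decide on a response in proportion. Over the 5508 genes called with miR2 in all tumours, which are chosen for their miR2 change, the median share was 0.206. A response in proportion and a response with a threshold each keep 1 direction with the 2 miRs. Against all 6 controls 26 genes passed in opposite directions, and against control tumours 2 and 5 alone 2 did. This argues against either response for those genes alone. For the other differences both responses stay open. The intensity distribution of the arrays is argued against as the whole cause, since 59.1% of the calls (2446) were shared, in the same direction, with those on quantile-normalized values, but 45.2% (1869) were shared with cyclic loess, so that it may account for part of them. A difference between the array sets is argued against as the whole cause, since 972 genes passed within set B alone. Of these, 95.8% (931) were among the 4136 in the same direction. The set B arrays are also part of the fit to all arrays, so this share follows largely from the design and adds no support. With the set as a block 54.9% of the 4136 (2271) were called, so that the sets may account for part. Effects of either hairpin on other transcripts were not tested apart from the hairpin.

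Other splits of the same tumours were tested for each count. For both miRs, 1 of 100 splits (the real one) gave as many as 3414 genes, and the highest other gave 1563. For miR1, 2 of 100 splits gave as many as 874, the real one included. The other gave 1586 and put control tumours 2 and 3 with miR1 tumours 1 to 4, which follows the array sets for all of these tumours but control tumour 1; within set A 10 genes and within set B 1 gene passed. For miR2, 2 of 84 splits gave as many as 5508; the other, with control tumour 5 in place of miR2 tumour 2, gave 7308 and points to a structure of the samples besides the groups. Between the miRs, 1 of 100 splits gave as many as 4136, and the highest other gave 2. These splits move tumours across the array sets. For both miRs and between the miRs no other split reached the real count, which argues against chance alone. For miR1 and for miR2 another split gave more genes than the real one, so chance is not excluded there. The counts against the controls also rest largely on control tumours 1, 3, 4 and 6. With tumours 2 and 5 alone they were 138, 25 and 803. The splits cannot tell loss of SHP2 from the difference of those 4 control tumours. Among splits that move tumours only within their set, 1 of 100 (the real one) gave as many as 3414 for both miRs. The highest other gave 1238. For miR1, 2 of 100 gave as many as 874, the real one included, and the other gave 1358. Chance is thus argued against for both miRs, with the same limit, and is not excluded for miR1. For miR2 and between the miRs set B leaves 20 splits of 3 against 3 tumours, too few for such a test.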
